A study of Homo sapiens with 6 samples.

How the data were processed

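Total RNA from 22RV1 cells was extracted with Trizol, and per the labels' protocols it was amplified into fluorescent cRNA with random primers and labelled with Cy3. The 6 arrays fall into a vehicle control group and a group treated with Robustanoids A, with 3 arrays each, as the sample titles and sources give them. The control's DMSO share of 0.1% equalled that of the treated wells per the labels.

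Per the file headers, each array was read in one colour with Agilent Feature Extraction 11.0.1.1 and a grid annotated for hg19. All 6 arrays were scanned together on 1 slide, the vehicle arrays and treated replicate 1 in row 1 and treated replicates 2 and 3 in row 2. The deposited spot values are intensity on a linear scale, and per the file headers the processed signal is already corrected for background but not normalized between arrays. The authors' value table holds log2 values. Each of its 6 columns had the same median of 5.78, and 92.9% of its ranks were equal in all columns within 0.01, as quantile normalization leaves them. Each column correlated best with its own array's log2 processed signal, with r of at least 0.997 against at most 0.988 for another array. It is thus on the log2 scale with no centring by gene, and the exact normalization is not given in the sources used here.

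Control spots were left out, as were spots that Feature Extraction marked as outliers. The log2 processed signal of each spot had the array's 75th percentile over the other 61482 spots subtracted. Spots of one probe were averaged, which gave 60728 probes, and 76 probes with no unmarked spot on some array were left out. A probe counted as well above background on an array if at least 50% of its spots did. The 53743 probes that were so on at least 3 of the 6 arrays were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with adjustment by Benjamini-Hochberg and a threshold of 0.05. No block entered the fit.

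Of all probes, 50 carried an accession in the files. Without version numbers, 49 matched a gene in the RefSeq table of GRCh38.p14, which was used for names only, and 1 did not. Each of these 49 genes had 1 probe printed 10 times. CD69 was well above background on no array, which left 48 genes. Their p-values were also adjusted over these genes alone. The other probes carry only the maker's identifiers, so counts of genes over the whole array, counts of lncRNAs, values for ASCC2 and TCONS_00027385 and tests of the fixed gene lists were not made. At most 3 genes of any list were measured, and at least 5 were needed.

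The genes to be named were chosen by a rule written before the data were examined. It takes up to 10 genes each way with the largest log2 fold. They need an adjusted p under 0.05, signal well above background on all arrays of a group and separate groups. It adds up to 4 members of each fixed list, where any passed only those with an adjusted p under 0.05. List membership added CHAF1B, so all 17 differing genes are named. CENPE did not pass while other members of its list did, so it is named outside the rule and given as a value. The rule did not provide for probes without a gene name. Up to 2 such probes each way were picked by the same conditions.

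The fit was tested on simulated arrays with the real probes' means and a spread drawn from the fitted model, alike in both groups. With 200 of 53743 probes changed, it recovered 0% of the changes of 1.41-fold, 14.9% of those of 2-fold and 84.8% of those of 4-fold, with 5 false calls among 71. With 20% of the probes changed, recovery was higher, at 54.9% for changes from 1.41-fold to 2-fold and 88.3% for those from 2-fold to 4-fold, and 3.87% of 4290 calls were false. With no change simulated it made 0 calls. The real groups differed in spread, with a median SD over the named genes tested of 0.053 in vehicle and 0.145 in treated arrays. These simulated shares thus hold for arrays that follow the model, and unequal spread or shifts of whole arrays were not simulated.

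The alternatives were quantile normalization, the authors' value table, other filters on dim probes, the replicate number as a block, an intensity trend with a robust prior, array weights, leaving out each array and minimum folds of 1.5 and 2. Normexp background correction with an offset of 50 was run on median spot signals, because the files used here have no mean spot signal. The offset is added to every signal and by itself shrinks the folds of dim probes. Slide row, marked spots and control-like identifiers were added after the data had been seen. Slide and scan could not serve as a block, since all arrays shared them.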

Results

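The series measured total RNA of 22RV1 cells, an established human prostate cancer cell line, on one-colour microarrays that the sample titles mark as lncRNA (long non-coding RNA) arrays. Cells received 10 µM of the compound Robustanoids A for 48 h, or 0.1% DMSO alone as the vehicle control. Each group had 3 arrays, and the labels do not say whether these came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The single comparison, treated against vehicle, asks which transcripts differ after exposure to the compound. The series title also names the lncRNA TCONS_00027385, the microRNA miR-874-5p and the gene ASCC2. The files used here pair no probe with any of these, so no value is given for them.

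The 3 vehicle arrays had a 75th percentile of processed signal of 194 ± 9.16 intensity units (SD, n = 3), against 163 ± 4.39 (SD, n = 3) in the treated arrays. The exact two-sided permutation test of this difference gave p = 0.1, the smallest value that 3 against 3 allows. Between 86.2% and 88.9% of the spots on an array were well above background, and no spot was saturated. That measure is lenient, since 47 of the 60 probes named Negative met it on at least 3 arrays and were tested, and 1 of them passed. The Pearson correlation over the tested probes was 0.991 for each pair of vehicle arrays and ranged from 0.986 to 0.991 between treated arrays and from 0.982 to 0.988 between groups. Among 49 probes printed 10 times, the median SD of log2 signal was 0.036 between spots of one array and 0.11 between arrays of one group. The median SE of a log2 fold was 0.16 over all tested probes and 0.12 over the 48 named genes that were tested.

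Treated cells had more signal for PLA2G4A and CCNA2 and less for DTL, BRCA1 and PRIM1 than vehicle cells. Of 48 genes that could be named and tested, 17 differed between the groups (limma, adjusted p under 0.05 over the 48 genes), 6 higher and 11 lower in treated cells. The gene with the largest increase was PLA2G4A, the cytosolic phospholipase A2 that releases arachidonic acid from membranes. Its log2 signal, relative to the array's 75th percentile, was 1.16 ± 0.048 in vehicle and 2.53 ± 0.13 in treated arrays (SD, n = 3), a 2.59-fold increase with an adjusted p of 0.00045. CCNA2, which encodes cyclin A2, followed with a 2.05-fold increase, from 2.31 ± 0.05 to 3.35 ± 0.15 (SD, n = 3, adjusted p = 0.0016). The largest decreases, of 1.78-fold, 1.78-fold and 1.74-fold, were in DTL, BRCA1 and PRIM1.

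The gene lists fixed before the data were examined had too few measured members for a test of any list, and the members that were measured are given here. Of the genes on the mitosis and G2/M list, which does not hold every such gene, 3 were measured. CCNA2 and KIF20A, a kinesin of late mitosis, were higher, KIF20A by 0.45 on the log2 scale (SE 0.11, adjusted p = 0.017). CENPE, a kinetochore motor, did not pass, at -0.10 (95% interval -0.36 to 0.17), and its sign turned to 0.04 with quantile normalization. Both measured genes of the DNA repair list, which does not hold every repair gene, were lower. Outside it RAD54B and SMC6 passed, and WRN at -0.16 and ABRAXAS1 at -0.21 did not (limma adjusted p = 0.27 and 0.20). BRCA1, which acts in homologous recombination, fell by 0.83 on the log2 scale (SE 0.15, adjusted p = 0.0072), and EXO1, a nuclease of mismatch repair and end resection, fell by 0.60 (SE 0.11, adjusted p = 0.0072). The measured gene of the DNA replication and G1/S list, CHAF1B, a subunit of the histone chaperone CAF-1, fell by 0.43 (SE 0.12, adjusted p = 0.032). In the mesenchymal list, LOX, a lysyl oxidase that cross-links collagen, was higher by 0.59 on the log2 scale (SE 0.11, adjusted p = 0.0072). LOXL2, a gene of the same family outside that list, was at -0.31 and did not pass (limma adjusted p = 0.057).

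**Figure D1:**
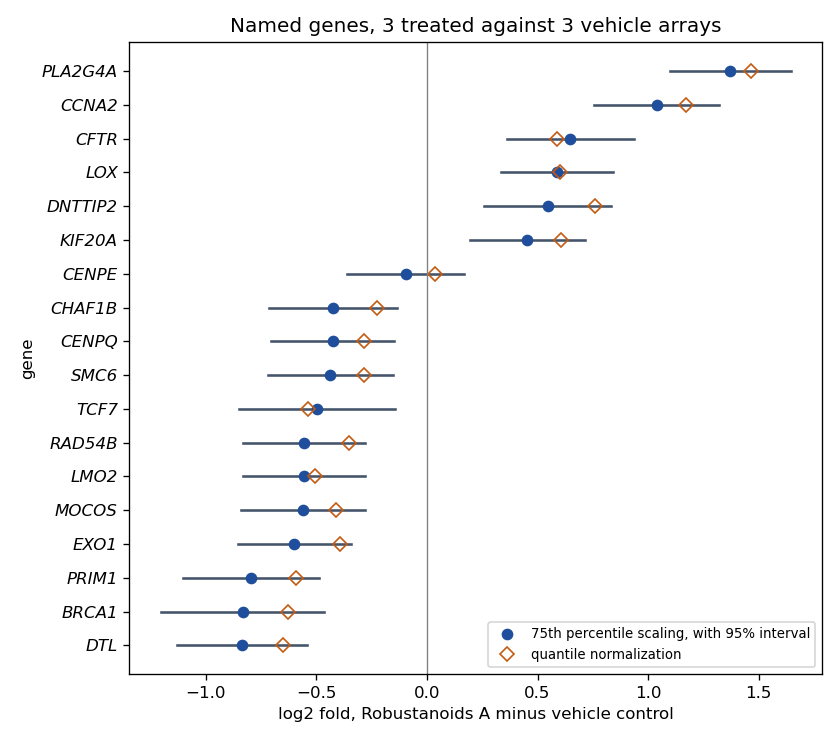
Log2 fold, treated minus vehicle, for the 18 named genes. Filled points with lines are values scaled to the 75th percentile with 95% intervals, and open diamonds are the folds after quantile normalization. PLA2G4A at 1.37 and CCNA2 at 1.04 lie farthest above 0, DTL at -0.84 lies farthest below, and only CENPE changes sign between the scalings.

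Outside these lists, DTL, the substrate receptor of a ubiquitin ligase that acts during DNA replication, fell by 0.84 on the log2 scale (SE 0.12, adjusted p = 0.0052). PRIM1, the catalytic subunit of DNA primase, fell by 0.79 (SE 0.13, adjusted p = 0.0066), and RAD54B, a recombination protein, fell by 0.56 (SE 0.11, adjusted p = 0.0098). SMC6, a subunit of a chromosome maintenance complex, fell by 0.44, and CENPQ, a centromere protein, by 0.43, with adjusted p = 0.028 for both. Lower signal was also measured for the molybdenum cofactor sulfurase MOCOS at -0.56, for the LIM-domain protein LMO2 at -0.56 and for the transcription factor TCF7 at -0.50. Their adjusted p were 0.0098, 0.0098 and 0.036. The size for TCF7 is uncertain, at -0.36 without treated replicate 1 and -0.57 without treated replicate 3. It was -0.21 with normexp background correction, whose offset of 50 by itself shrinks the folds of dim probes. Beside PLA2G4A, CCNA2, KIF20A and LOX, the genes with higher signal were CFTR, a chloride channel, at 0.65 (adjusted p = 0.0072) and DNTTIP2, a nucleolar protein, at 0.55 (adjusted p = 0.012). The size and direction of the CFTR change are uncertain, since its probe lay below the median of the Negative probes on all 3 vehicle arrays and on treated replicate 1 (-3.45 against -2.78). The log2 fold was 0.25 with normexp and 0.11 (adjusted p = 0.239) with normexp and quantile normalization, and an intensity trend with a robust prior gave an adjusted p of 0.125. The smaller normexp folds come at least partly from the offset of 50. In each of these 17 genes all treated values lay on one side of all vehicle values. The same held in 31 of the 48 genes, or 64.6%, and in 25.4% of all tested probes, against 10% by chance for 3 against 3.

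**Figure D2:**
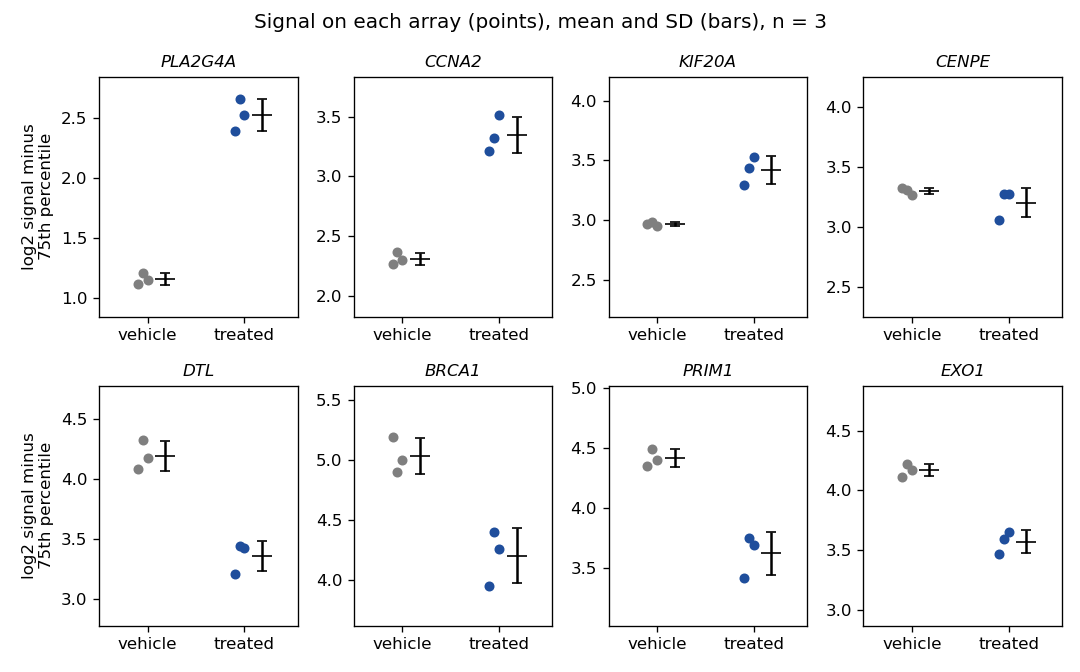
Log2 signal minus the array's 75th percentile for 8 of the named genes, with a point for each array and bars for the mean and SD of the 3 arrays in a group. Each panel spans the same range of log2 units, and the groups separate in all panels except that of CENPE.

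Adjusted over all 53743 probes tested on the arrays, 8 of these genes remained under 0.05: PLA2G4A, CCNA2, CFTR, LOX, EXO1, PRIM1, BRCA1 and DTL. The named genes were mostly bright, and the median log2 fold of all 48 was -0.16, close to the -0.13 of the brightest 20% of all probes. With quantile normalization 20 genes differed, 10 higher and 10 lower, of which 14 were among the 17. CFTR (0.59), TCF7 (-0.54) and CHAF1B (-0.23) then missed the threshold, and the log2 folds of CHAF1B, EXO1 (-0.39), RAD54B (-0.35), SMC6 (-0.29) and CENPQ (-0.28) were smaller by over 1.5 times. Leaving out 1 vehicle array gave 10 genes without replicate 1, 12 without replicate 2 and 11 without replicate 3. Leaving out 1 treated array gave 13, 25 and 12 genes without replicates 1, 2 and 3. With the row of the array on the slide as a block, 13 of the 17 genes passed, KIF20A (0.33), DNTTIP2 (0.39), CFTR (0.52) and CENPQ (-0.53) not among them. Row 2 held treated arrays only. The folds of that fit thus come from treated replicate 1 against the vehicle arrays, as they do within slide row 1 alone. Within slide row 1 the spread comes from the vehicle arrays only, whose median SD over the 48 genes was 0.053 against 0.145 in the treated arrays. A fit there understates the spread.

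Over the whole array, 2199 of 53743 probes differed between treated and vehicle cells (limma, adjusted p under 0.05), 858 higher and 1341 lower. That is 4.09% of the probes tested, and the lowest adjusted p was 0.0012. The median size of change among them was 1.78-fold. At least a 2-fold change was seen in 336 higher and 324 lower probes, and at least a 4-fold change in 76 higher and 26 lower probes. An unadjusted p under 0.05 was found for 9876 probes, where 2687 would be expected by chance. All 3 treated values lay on one side of the vehicle values in 25.4% of the tested probes, against 10% by chance.

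The probes with the largest changes that were well above background on all arrays of a group carried only the maker's identifiers, which the files do not pair with genes. Probe ASHG19LNC1A104416893V5 was 20.2-fold lower, from 3.91 ± 0.26 in vehicle to -0.42 ± 0.16 in treated arrays (SD, n = 3, limma adjusted p = 0.0012). Probe ASHG19AP1B100112039V5 was 10.3-fold lower, from 4.13 ± 0.19 to 0.76 ± 0.17 (SD, n = 3, adjusted p = 0.0012). Probe ASHGV40052634V5 was 15.7-fold higher, a log2 fold of 3.98 (SE 0.27, adjusted p = 0.0040), but the log2 fold was 2.67 with normexp, and with the slide row as a block it was 4.10 (adjusted p = 0.0614). Probe ASHG19LNC1A100041168V5 was also higher (adjusted p = 0.039), with a log2 fold of 3.97, or 1.51 with normexp. For both higher probes the normexp offset of 50 by itself shrinks the fold, since their mean vehicle signals were 38.4 and 11.7 intensity units. The size for ASHG19LNC1A100041168V5 is uncertain on other grounds. Its vehicle SD was 1.52, it lay below the median of the Negative probes on all 3 vehicle arrays, and it missed the threshold in 5 of the 6 fits that left out an array.

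Probe identifiers fell into families by their first characters, whose meaning the files do not state. Among probes starting with ASHG19AP1B, 926 of 19699 differed (4.70%), against 875 of 22779 (3.84%) of those starting with ASHG19LNC1A, leaving out the ASHG19LNC1ABL probes (45 of 868). The odds ratio was 1.23 (95% interval 1.12 to 1.36, Fisher's exact test, two-sided, p = 1.23e-05), with probes that are not independent of each other. Within 5 equal classes of brightness the odds ratio (Mantel-Haenszel) was 0.97 (95% interval 0.88 to 1.07). Of the family starting with ASHGV4, 343 of 10184 probes differed (3.37%).

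The balance of higher and lower probes depended on the scaling: 61.0% of the differing probes were lower with the 75th percentile, and 47.4% of 3440 were lower with quantile normalization. With the slide row as a block, a fold that again rests on treated replicate 1, 13 probes passed (11835 at an unadjusted p under 0.05), and within slide row 1, which held all vehicle arrays and treated replicate 1, limma found 0 (13586 unadjusted). The count was 189, 192 and 194 without vehicle replicates 1, 2 and 3, and 711, 3531 and 145 without treated replicates 1, 2 and 3. Of the 2199 probes, 124 passed in all 6 of these fits.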

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

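The test of the slide row, the test of chance for the named genes and the test of the PGK1_5 probe against probes of like brightness were written down before their results were seen. All other tests of an explanation in this part were chosen after the result was seen. The settings with quantile normalization, the replicate number as a block or an array left out were planned beforehand, and the fits by slide row were not.

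The PGK1_5 features, which lie outside the main measurement, were higher in treated than in vehicle arrays. They belong to 12 control features that carry the gene names PGK1 and GAPDH, the only control features named for genes, and each was printed 10 times. PGK1 encodes the glycolytic enzyme phosphoglycerate kinase 1. The log2 fold was 0.40 for Human-PGK1_5 (SE 0.10), 0.39 for Mouse-PGK1_5 and 0.36 for Rat-PGK1_5, with all treated values above all vehicle values and a limma adjusted p of 0.039 over the 12 features for each. All RNA came from human cells and the same 6 arrays, so the features named for mouse and rat are not separate results. Over the 4 human features alone the limma adjusted p of Human-PGK1_5 was 0.024. Human-GAPDH_3 was at -0.09 and Human-GAPDH_5 at -0.02, and neither passed. Mouse-PGK1_3 at 0.34 (95% interval 0.07 to 0.60, adjusted p = 0.058), Rat-GAPDH_3 at 0.31 and Mouse-GAPDH_3 at 0.25 also had all treated values above all vehicle values and did not pass. With quantile normalization both human GAPDH features turned positive, to 0.19 and 0.23, and Human-GAPDH_5 then passed when adjusted over the 4 human features (limma adjusted p = 0.041).

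A shift common to probes of like brightness is argued against for Human-PGK1_5, since 1715 probes within 0.25 log2 units of its level had a median log2 fold of -0.039, below its 95% interval of 0.16 to 0.64. Human-PGK1_5 was flagged because it passed, so an interval above 0 was set beforehand and the comparison says no more than this. Human-PGK1_5 lay at percentile 92.9 among these probes, so others of like brightness rose as much. The files do not say what the suffixes 3 and 5 mean, and a shift between the suffixes common to both genes, from labelling or RNA integrity, stays open. The difference of Human-GAPDH_5 and Human-GAPDH_3 shifted by 0.07 (95% interval -0.03 to 0.17), and that of the PGK1 pair by 0.27 (95% interval -0.08 to 0.62). The mouse and rat GAPDH features went the other way, with log2 folds of -0.13 and -0.03 for suffix 5 against 0.25 and 0.31 for suffix 3. For PGK1 suffix 5 was again the higher, at 0.39 against 0.34 in mouse and 0.36 against -0.06 in rat. The rat contrast says little, since Rat-PGK1_3 lay below the median of the Negative probes on every array (95% interval -0.74 to 0.62). The hypothesis that treated cells hold more PGK1 transcript also stays open, because Human-PGK1_3 was at 0.13 (95% interval -0.16 to 0.42). With quantile normalization it was at 0.42 and passed (limma adjusted p = 0.0065). That scaling also moved Human-GAPDH_3 from -0.09 to 0.19, so the gain is not particular to PGK1. The call for Human-PGK1_5, adjusted over the 4 human features, was lost in 5 of the 6 fits that left out an array, with limma adjusted p from 0.0542 to 0.115. The fit without treated replicate 2 kept the call (adjusted p = 0.0433). With the slide row or the replicate number as a block the call was lost as well. The log2 fold stayed between 0.36 and 0.44 in all these fits and within slide row 1.

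For the 2199 probes that differed between the groups, the place of an array on the slide was weighed, since treated replicates 2 and 3 lay in another row than all vehicle arrays. The 500 probes with the lowest p in a fit of treated replicates 2 and 3 against 2 vehicle arrays were compared in treated replicate 1 and the remaining vehicle array, both in row 1. Between 89.6% and 90.8% of them had the same direction there, which argues against the slide row as the whole source of the differences among these probes. The 10 ways to split 6 arrays are too few for a share under 0.05. The real split gave 2199 probes and 17 named genes, counts that 1 split reached in each case, and the highest of the other splits gave 0 probes (3677 at an unadjusted p under 0.05) and 0 named genes (0 unadjusted) with limma.

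Among the named genes, the pattern of higher CCNA2 and KIF20A with lower BRCA1 and EXO1 was weighed against brightness-dependent scaling and a change in the cell cycle. All 4 of these genes had a 95% interval that excluded the median log2 fold of probes of like brightness, which lay between -0.18 and -0.12. The genes had been picked for passing, so intervals away from 0, and from medians near 0, were likely beforehand. Among probes of like brightness CCNA2 lay at percentile 99.2, KIF20A at 96.0, BRCA1 at 5.29 and EXO1 at 11.9. A shift of the size of these medians thus does not make up the whole of the 4 changes, and the test says no more about scaling. For CHAF1B the interval of -0.71 to -0.14 included that median of -0.17, so the scaling stays open there. The change of CCNA2 exceeded that of CENPE by 1.14 on the log2 scale (95% interval 0.88 to 1.39), which decides nothing about the cell cycle, since CCNA2 was picked as the gene of this pattern with the largest change. A larger share of cells in G2 or M, a smaller share in S phase and a change in single genes stay open as untested hypotheses.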

How the results depend on the processing

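Slide row, normexp on median signals, marked spots and control-like identifiers were chosen after seeing the data. No named gene, named probe or human PGK1 feature that passed reversed with other scaling or signal values; in the other fits their separated groups fixed the sign. Of 480 values for these and the GAPDH features, 405 stayed on their side of the threshold, 68 missed it and 7 newly passed it. The main count was 2199 probes, 858 higher and 1341 lower, and 17 genes.

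Quantile normalization gave 3440 probes (1811 higher) and the authors' values gave 3488 (1853 higher). Without a filter on dim probes 1464 passed (578 higher, 886 lower), with 60652 probes tested, and with only probes well above background on all 6 arrays 2724 passed (1028 higher, 1696 lower), with 48946 tested, and 18 genes. An intensity trend with a robust prior gave 5474 (2087 higher, 3387 lower). Array weights gave 18156 (7835 higher, 10321 lower) and 35 genes, but the weights stopped short of their tolerance and put 20.1 on treated replicate 3 alone. Normexp gave 7893 (3269 higher, 4624 lower) and 32 genes with the 75th percentile, and 7100 (3670 higher, 3430 lower) with quantile normalization. For these settings the cause was not tested. A minimum of 2-fold left 660 probes (336 higher, 324 lower) and 2 genes, and 1.5-fold left 8 genes. An unadjusted p with at least 2-fold gave 911 probes (440 higher, 471 lower) and 2 genes.

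With the replicate number as a block, limma gave 0 probes, 0 higher and 0 lower (9330 at an unadjusted p under 0.05), and 16 genes, TCF7 missing the threshold. The labels give the arrays only a shared number: deviations of same-numbered arrays correlated at -0.033, 0.067 and 0.004, and not every array correlated best with its own number. The slide row as a block gave 13 probes, 4 higher and 9 lower, and slide row 1 alone gave 0 probes, 0 higher and 0 lower (13586 unadjusted), with 1 treated array assumed to vary like the vehicle arrays. Both fits leave fewer degrees of freedom, and both take the fold from treated replicate 1 alone, since row 2 held no vehicle array.

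Leaving out each array gave 145 (without treated replicate 3) to 3531 probes (without treated replicate 2), 67 to 1209 higher, 78 to 2322 lower, and 10 (without vehicle replicate 1) to 25 genes (without treated replicate 2). In all 6 such fits 10 genes passed: PLA2G4A, CCNA2, CFTR, LOX, RAD54B, LMO2, EXO1, PRIM1, BRCA1 and DTL. MOCOS was lost without vehicle replicate 1, DNTTIP2 without vehicle replicate 1 or 3, and KIF20A without any vehicle replicate or treated replicate 3. CHAF1B, CENPQ, SMC6 and TCF7 were lost without any array but treated replicate 2.

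Not run were normexp on mean spot signals, which the files used here do not hold, slide or scan as a block, the mean over probes of a gene, since each gene had 1, and all alternatives for lncRNA counts, ASCC2, TCONS_00027385 and gene lists. Signal over background limits dim probes: CFTR was well above background on 2 of the 3 vehicle arrays, below the median of the Negative probes on all 3 and on treated replicate 1, and fell to 0.11 (adjusted p = 0.239) with normexp and quantile normalization. The normexp offset of 50 by itself shrinks the folds of such probes.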

Other observations

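Detection on one side only was more frequent than in other groupings of the arrays. There were 95 probes well above background on all treated and no vehicle arrays, and 100 with the reverse. These 195 probes compare with 85 to 137 in the other splits of the 6 arrays into groups of 3.

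The arrays of the treated group were less alike than those of the vehicle group. The first principal component held 38.4% of the variance and placed the vehicle arrays between -45.2 and -33.3 and treated replicates 1, 2 and 3 at 70.5, -0.3 and 43.3. The median absolute log2 difference between 2 arrays was 0.15 to 0.17 within the vehicle group, 0.20 to 0.32 within the treated group and 0.24 to 0.32 between groups. In the brightest 20% of probes the median level was 3.01 to 3.06 in vehicle arrays and 2.75, 3.04 and 2.85 in treated replicates 1, 2 and 3.

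Among the other named genes, 6 that were not among the 17 passed with quantile normalization: EIF5B at 0.42, POGLUT2 at 0.35, RPAP3 at 0.35, ERGIC2 at 0.35, PIMREG at 0.29 and COL13A1 at -0.38. These were chosen after their values were seen. All 6 also passed with the authors' values, but those have ranks as quantile normalization leaves them and are no separate check. Of the 19 other settings run, PIMREG, ERGIC2 and POGLUT2 passed in 3, all with this kind of scaling. RPAP3 and EIF5B passed in 4, with array weights as the added setting. COL13A1 passed in 9, among them that with outlier spots kept. EIF5B encodes a translation initiation factor. With the 75th percentile their limma adjusted p over the 48 genes ranged from 0.0515 (COL13A1, at -0.36) to 0.524 (PIMREG, at 0.08).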
